A study of Mus musculus with 6 samples.

How the data were processed

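Gene expression was measured on 6 mouse Affymetrix arrays, 3 of cells labelled Cre-ERT2 and 3 of cells labelled ERT2 control, with group and replicate number taken from the sample labels. The deposited values are on the log2 scale, 1 value for each of 35556 probe sets on each array. RMA, which corrects the background, normalizes between arrays and summarizes probes, and Partek 6.5 are named in the submitters' processing notes, without their order, role or settings. Probe-level files were not used here, so the background correction and the summarization could not be varied. The genome build is not given in the sources used here, so no coordinates are printed. Values had no missing or negative entries, ranged from about 2.9 to 14.9, and were used as deposited.

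Probe sets were named through the annotation table of the array: 21789 carried 1 gene symbol, 1621 carried several and were not used for named genes, and 12146 were not named by the table. Entrez identifiers of 21698 named probe sets were found in the RefSeq gene table, and 0 symbols were updated. For a gene with more than 1 probe set (999 of 19938 genes), the probe set with the highest mean over all 6 arrays was used. Among the genes called, 80 had more than 1 probe set, and in 10 of these a probe set had the opposite sign. The 4985 genes whose mean lay below the 25th percentile (a log2 value of 7.35) were left out, which left 14953. Normalized array values carry no count depth, and 3 arrays per group limit the precision.

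The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 4.31 prior degrees of freedom), two-sided, as labelled Cre-ERT2 minus ERT2 control, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are differences of group means of log2 values, and standard errors are those of the moderated fit. No covariate was fitted, since the labels give none, and no scan date, slide or other batch label was used here. Gene lists were tested with limma's camera, with a preset inter-gene correlation of 0.01 and adjustment over all 23 lists, and with fry beside it. Counts of list members are given over all genes and adjusted over the list alone. The lists held 589 entries, of which 543 were on the array: cholesterol and fatty acid synthesis, glycolysis, oxidative phosphorylation, MYC targets and ribosome biogenesis, S phase and DNA replication, G2 and mitosis, interferon response, STAT5 targets, NF-kB targets, p53 targets, B lineage transcription factors, pre-B cell receptor and proximal signalling, inhibitory receptors and phosphatases, B cell maturation and antigen presentation, FOXO-activated genes, ERK-induced genes, BCL2 family and cell death, unfolded protein and ATF4 response, antioxidant and NRF2 targets, and markers of myeloid, T and NK, erythroid and megakaryocyte, and stromal cells. Some genes are in more than 1 list (Cd5, Rag2, Sesn2 and Bcl2l11 among those named).

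The tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took Inpp5d; the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05 and no overlap between the groups, leaving out clone and predicted names (44 of the genes called had such names); up to 4 members of each list with the smallest p; and a fixed set of signalling, cell cycle and B lineage genes, of which 3 are not analysed here. It gave 118 genes, of which the text names those of most use; genes outside the rule are said to have been chosen after the data were seen.

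Alternatives were no filter on dim genes, a filter at the 50th percentile, the mean of all probe sets of a gene, quantile normalization run again, centring of each array on the median, eBayes with trend and robust estimation, array weights, the replicate number as a block, each array left out in turn, a 2-fold minimum, a threshold of 0.01, all probe sets in place of genes, and camera with the correlation estimated for each list. Intensity-dependent loess between arrays (cyclic loess of limma) was added after seeing the data. Lists were also compared with 10000 random lists of the same size, matched on mean expression in 20 bins, which treats genes as independent. Further groups of genes (Y-linked, X-inactivation escape, miR-17-92, nuclear-retained RNAs, hypoxia-induced and further lipid genes) were written after the data were seen. The procedure was tested on simulated data for the same comparison over 14953 genes: it recovered 82% of 100 genes changed by 0.5 and 98% of 100 genes changed by 1 on the log2 scale, with 11 false calls, and in a simulation in which 1 list was shifted by -0.2, that list alone was called. Simulated genes varied independently and had no difference tied to brightness, so camera was not tested on lists of correlated genes. Recovery of single genes changed by less than 0.5 was not measured. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.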

Results

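RNA from pre-B cells transformed with BCR-ABL1, the kinase fusion of Philadelphia chromosome-positive acute lymphoblastic leukaemia, was profiled on 6 mouse Affymetrix arrays. All cells carried floxed alleles of Inpp5d, which encodes SHIP1, a lipid phosphatase that removes the 5-phosphate from the PI3K product PIP3. Cells on 3 arrays had been transduced with a tamoxifen-activated Cre recombinase (labelled Cre-ERT2) and cells on 3 arrays with the tamoxifen-binding domain alone (ERT2 control). Both groups received 4-hydroxytamoxifen at 0.5 µM, and RNA was taken from puromycin-resistant cells after 2 days. The design therefore asked which transcripts differed between cells given Cre and cells given the control construct. It held no arm with Cre but without floxed alleles and no arm without tamoxifen, so effects of Cre activity itself were not separated from loss of Inpp5d. The labels do not say that the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Pearson's r between arrays, taken across probe sets that are not independent replicates, ranged from 0.988 to 0.997, and no pair shared more than 30 identical values of 35556. The array labelled Cre-ERT2 3 correlated more closely with ERT2 control arrays 3 and 1 (r = 0.9967 and 0.9963) than with the other arrays of its own group (0.9938 and 0.9950). The number of arrays limits the precision of every value. The median log2 value was 8.21, 8.19 and 8.23 in ERT2 control arrays 1, 2 and 3, and 8.37, 8.32 and 8.24 in the arrays labelled Cre-ERT2 1, 2 and 3.

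The targeted gene was not lower in the arrays labelled Cre-ERT2. Inpp5d had a log2 value of 13.35 ± 0.013 (SD, n = 3) in the arrays labelled Cre-ERT2 and 13.19 ± 0.020 (SD, n = 3) in the ERT2 control arrays, and its probe set was brighter than 98.8% of genes. The individual log2 values of Inpp5d were 13.37, 13.34 and 13.34 in the arrays labelled Cre-ERT2 and 13.20, 13.21 and 13.17 in the controls. The difference of 0.16 ± 0.041 (SE) on the log2 scale, with a 95% interval from 0.064 to 0.25, did not pass limma's test (adjusted p = 0.0545). All 3 arrays labelled Cre-ERT2 lay above all 3 controls for Inpp5d. The array measured Inpp5d with 1 probe set, and whether that probe set covers the deleted exons is not given in the sources used here; if it lies outside them, it checks nothing about recombination. Inpp5d passed under other processing, in the same upward direction, with adjusted p from 0.00364 to 0.0485 in 5 settings, and its difference was 0.056 when arrays were centred on their medians (adjusted p = 0.595). Because the signal of the target runs against the label, groups are named by their labels throughout, and each direction given here is that of the arrays labelled Cre-ERT2 relative to the ERT2 control arrays.

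The largest fall in the arrays labelled Cre-ERT2 was that of Cdh1, which encodes the adhesion molecule E-cadherin. Its log2 value was 8.28 ± 0.015 (SD, n = 3) against 10.28 ± 0.026 in the controls, 4.00-fold lower (limma adjusted p = 3.08e-07). Rtn1, which encodes a protein of the endoplasmic reticulum, was 3.33-fold lower (log2 fold change -1.73 ± 0.054, SE), and Emb, which encodes a partner protein of monocarboxylate transporters, was 2.60-fold lower (-1.38 ± 0.12). Scd1, which encodes the desaturase that makes monounsaturated fatty acids, was 2.53-fold lower (-1.34 ± 0.044), and Idh1, which encodes the cytosolic NADP-dependent isocitrate dehydrogenase, was 2.05-fold lower (-1.04 ± 0.10). The largest rise was that of Ly6f, a member of the Ly6 family of surface proteins, at 2.42-fold higher (1.28 ± 0.10, adjusted p = 9.35e-04).

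Among the other large rises, Pir, which encodes the iron-binding nuclear protein pirin, was 1.90-fold higher, the lysozyme gene Lyz2 1.73-fold higher and Xist, the non-coding RNA of X inactivation, 1.62-fold higher. P2rx3, which encodes an ATP-gated channel, the AP-1 gene Fosb, the phosphatase gene Ptpn14, the immune checkpoint gene Vsir, the interferon-induced Usp18 and the growth factor gene Igf1 rose by log2 fold changes of 0.68, 0.66, 0.66, 0.65, 0.65 and 0.64. Scarna13 and Malat1, both nuclear non-coding RNAs, rose by 0.67 and 0.63. Among the other large falls, Ak4, which encodes a mitochondrial adenylate kinase, had a log2 fold change of -1.61, the microRNA gene Mir19a -1.10 and the small nucleolar RNA gene Snord118 -1.01. The nucleic acid sensor gene Tlr7, the palmitoyltransferase gene Zdhhc2, the calcium sensor gene Ncs1 and the purine receptor gene P2ry13 had log2 fold changes of -0.93, -0.92, -0.91 and -0.90. Of these 24 genes with the largest changes, 21 kept an adjusted p under 0.05 in each of the 15 other settings of filter, scaling, model or arrays in which they were tested; a 2-fold minimum was met by 9. Malat1 lost its call in 8 settings, Snord118 in 5 and Scarna13 in 3. The second probe set of Ak4 had a log2 fold change of -0.15, and the mean of both -0.88, so the size of its fall rests on 1 of 2 probe sets.

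**Figure D1:**
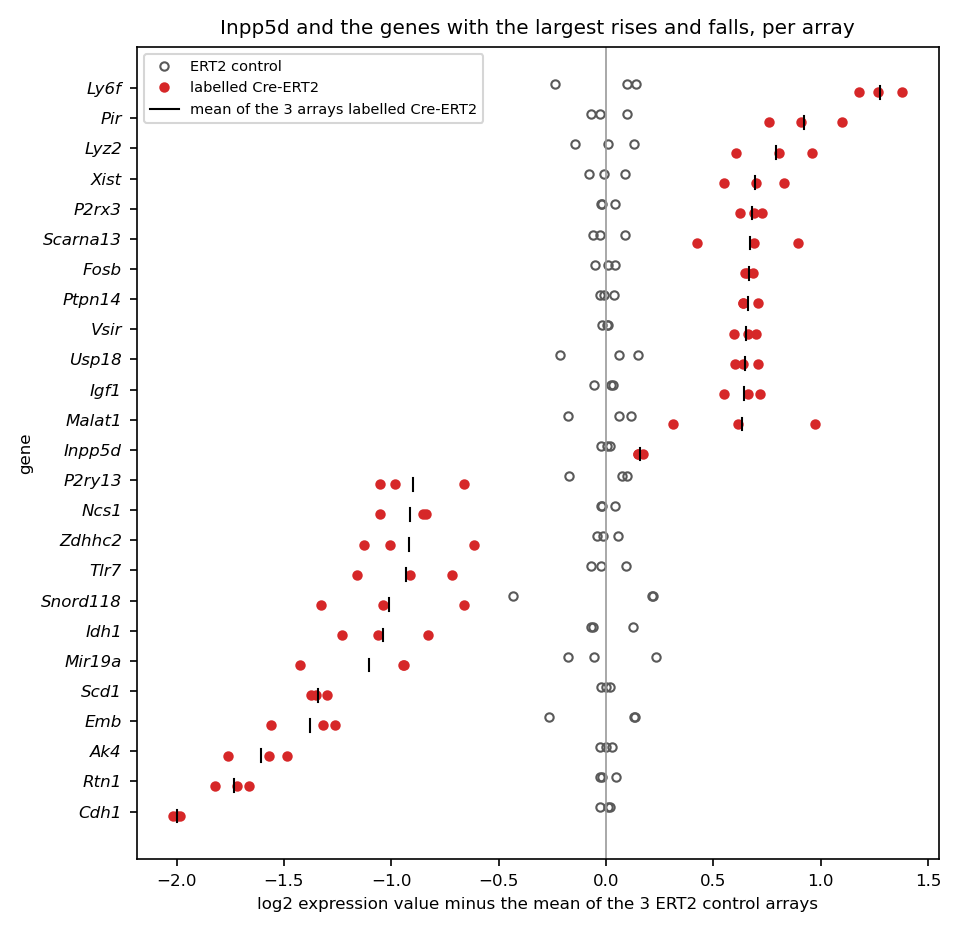
Log2 value of each array minus the mean of the 3 ERT2 control arrays (horizontal axis) for Inpp5d and the 24 genes with the largest changes (vertical axis); open grey circles are ERT2 control arrays, red circles arrays labelled Cre-ERT2 and black bars their mean. Inpp5d lies 0.16 above the controls, while Cdh1 lies 2.00 below them.

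In all, 1140 of 14953 genes tested (7.62%) differed at an adjusted p under 0.05, with 523 higher and 617 lower in the arrays labelled Cre-ERT2. Most of these differences were small, with a median absolute log2 fold change of 0.28, and 9 genes (1 higher and 8 lower) changed at least 2-fold. In all 1140 genes the 3 values of each group did not overlap, and the same held for 38.5% of all genes tested, against 10% by chance for a gene taken alone. The 10% takes no account of array-wide differences tied to brightness, which can separate the groups for many genes at once. In bin 3 of 10 by brightness, the median deviation was -0.073, -0.057 and -0.025 in the controls. It was 0.063, 0.11 and -0.011 in the arrays labelled Cre-ERT2. The excess over 10% therefore does not count separate gene effects. The count of genes called varied with the arrays used: it was 116, 194 and 347 without ERT2 control array 1, 2 or 3, and 136, 525 and 3042 without the array labelled Cre-ERT2 1, 2 or 3. Fits with an array left out hold 2 arrays in 1 group and have fewer residual degrees of freedom. A call lost in such a fit may reflect lower power and does not by itself mean dependence on that array. Lower power does not account for the rise to 3042 genes without the array labelled Cre-ERT2 3. As given above, that array correlated more closely with ERT2 control arrays 3 and 1 than with its own group. Centring the arrays on their medians moved the median log2 fold change of all genes from 0.026 to -0.077 and gave 223 higher and 2797 lower (7.38% higher) in place of 45.9% higher.

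Genes of cholesterol and fatty acid synthesis fell together in the arrays labelled Cre-ERT2. Of 23 members tested, 17 were lower, 0 higher and 6 did not pass (adjusted over the list alone, 19 lower and 0 higher), with a median log2 fold change of -0.37. Besides Scd1, the desaturase gene Scd2 fell by 0.60 ± 0.052 (SE) on the log2 scale, Lss, which encodes lanosterol synthase, by 0.54 ± 0.053, and Insig1, which encodes a sterol-regulated brake on SREBP processing, by 0.53 ± 0.052. The camera test on the list gave an adjusted p of 1.52e-16, and adjusted p = 0.0975 with an estimated correlation. Scd1, Scd2, Lss and Insig1 passed with each array left out in turn.

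Glycolysis genes were also lower in the arrays labelled Cre-ERT2. Of 17 members tested, 10 were lower, 0 higher and 7 did not pass (adjusted over the list alone, also 10 lower and 0 higher). The lactate exporter gene Slc16a3 had a log2 fold change of -0.49 ± 0.045 (SE), the aldolase gene Aldoc -0.44 ± 0.057, the phosphofructokinase gene Pfkl -0.43 ± 0.050 and the triosephosphate isomerase gene Tpi1 -0.34 ± 0.046. By camera the list had an adjusted p of 2.75e-07, and adjusted p = 0.233 with an estimated correlation. Slc16a3, Aldoc and Pfkl passed with each array left out, whereas Tpi1 did not pass without ERT2 control array 1 (adjusted p = 0.0522).

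Oxidative phosphorylation genes showed a small shift in the same direction. Of 28 members tested, 1 was lower, 0 higher and 27 did not pass (adjusted over the list alone, 3 lower and 0 higher), with a median log2 fold change of -0.11. Ndufa4, which encodes a small protein of the respiratory chain, had a log2 fold change of -0.27 ± 0.064 (SE, adjusted p = 0.0412), and the complex I gene Ndufv1 had -0.21 (adjusted p = 0.0532), which did not pass. As a list they had a camera adjusted p of 1.01e-04, and adjusted p = 0.320 with an estimated correlation. Ndufa4 passed in 1 of 6 fits with an array left out, the fit without the array labelled Cre-ERT2 3.

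In each of 3 lists of growth and division genes, 3 members were lower in the arrays labelled Cre-ERT2, 0 were higher and the others did not pass. Myc itself fell by 0.22 ± 0.042 (SE) on the log2 scale (limma adjusted p = 0.0259). Of 29 tested MYC targets and ribosome biogenesis genes, 3 were lower, 0 higher and 26 did not pass (adjusted over the list alone, 10 lower and 0 higher): the purine synthesis gene Ppat (-0.28), and Rrp9 (-0.25) and Nop58 (-0.19), which encode ribosomal RNA processing factors. Camera gave this list an adjusted p of 1.75e-05, and adjusted p = 0.233 with an estimated correlation. Of 31 tested S phase and DNA replication genes, 3 were lower, 0 higher and 28 did not pass (adjusted over the list alone, also 3 lower and 0 higher): the flap endonuclease gene Fen1 (-0.44), the clamp loader gene Rfc3 (-0.30) and Gins1, of the replicative helicase (-0.30). For this list the camera adjusted p was 2.04e-05, and adjusted p = 0.233 with an estimated correlation. Of 31 tested G2 and mitosis genes, 3 were lower, 0 higher and 28 did not pass (adjusted over the list alone, also 3 lower and 0 higher): the mitotic kinase gene Nek2 (-0.29), the kinesin gene Kif2c (-0.26) and Birc5, which encodes survivin (-0.20). Its camera adjusted p was 0.00769, and adjusted p = 0.488 with an estimated correlation, and its call ended after quantile normalization (adjusted p = 0.135), after loess between arrays (0.199) and with the stricter filter on dim genes (0.171); fry did not call it (0.117). Each of the genes named here with a value lost its call with at least 3 of the 6 arrays left out, among them both ERT2 control array 1 and the array labelled Cre-ERT2 1.

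Of the interferon response, STAT5 target and NF-kB target lists, 7, 4 and 1 members were higher in the arrays labelled Cre-ERT2 and 0 were lower. Of 24 interferon response genes tested, 7 were higher, 0 lower and 17 did not pass (adjusted over the list alone, 11 higher and 0 lower). Usp18, which encodes a protease that removes ISG15, rose by 0.65 ± 0.089 (SE) on the log2 scale, Ifit3 by 0.50 ± 0.095, the transcription factor gene Irf7 by 0.44 ± 0.065 and the RNA sensor gene Ddx58 by 0.24 ± 0.048. The camera adjusted p was 6.16e-04, and adjusted p = 0.233 with an estimated correlation. Of 16 STAT5 target genes, 4 were higher, 0 lower and 12 did not pass (adjusted over the list alone, 5 higher and 0 lower). They were the interleukin-2 receptor gene Il2ra (0.40 ± 0.052) and 3 feedback inhibitors of cytokine signalling, Socs1 (0.31), Socs3 (0.25) and Cish (0.23). For the STAT5 list the camera adjusted p was 0.0298, and adjusted p = 0.233 with an estimated correlation. Of 18 NF-kB target genes, 1 was higher, 0 lower and 17 did not pass (adjusted over the list alone, also 1 higher and 0 lower): the cytokine subunit gene Ebi3 (0.25). Its camera adjusted p was 0.0382, and adjusted p = 0.233 with an estimated correlation. The STAT5 call ended without the array labelled Cre-ERT2 3 (adjusted p = 0.0960), after centring (0.0804) and with array weights (0.0508), and the NF-kB call without ERT2 control array 1 (0.0508) or 3 (0.0516), without the array labelled Cre-ERT2 3 (0.0960), without the filter on dim genes (0.0894) and after centring (0.101). Usp18 passed with each array left out, Il2ra failed without ERT2 control array 1 (adjusted p = 0.0542), Irf7 failed without the array labelled Cre-ERT2 1 (0.0597), and the other genes named here passed in at most 3 of 6 such fits.

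Of 26 B lineage transcription factors tested, 3 were higher in the arrays labelled Cre-ERT2, 0 lower and 23 did not pass (adjusted over the list alone, 5 higher and 1 lower). As a list they were higher by camera (adjusted p = 0.0382), and adjusted p = 0.233 with an estimated correlation. Id2, which encodes an inhibitor of E proteins, rose by 0.41 ± 0.088 (SE) on the log2 scale, Bach2, which encodes a repressor active in pre-B cells, by 0.27 ± 0.055, and the Ikaros family gene Ikzf3 by 0.19 ± 0.047. Pax5, which encodes a factor of B cell identity, had a log2 fold change of -0.0021 (adjusted p = 0.979) and Bcl6, a repressor gene, 0.10 (adjusted p = 0.162); neither passed, and the sign of Pax5 turned after quantile normalization and loess and that of Bcl6 after quantile normalization and centring. The list call ended without ERT2 control array 3 (0.0567) or the array labelled Cre-ERT2 3 (0.134), without the filter on dim genes (0.0763), after centring (0.159) and with array weights (0.0713), and Id2, Bach2 and Ikzf3 each lost their calls with at least 4 of the 6 arrays left out.

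For the pre-B cell receptor pathway, its inhibitors and B cell maturation, single genes passed and neither camera nor fry called a list. Of 18 tested genes of pre-B cell receptor and proximal signalling, 1 was higher, the kinase gene Prkcb (0.19), 0 lower and 17 did not pass (adjusted over the list alone, 1 higher and 1 lower), and the camera adjusted p was 0.527. The kinase genes Syk (0.044) and Btk (0.018) and the adaptor gene Blnk (0.089) did not pass, and their log2 fold changes turned negative after centring. Of 22 inhibitory receptors and phosphatases, 1 was higher, 2 lower and 19 did not pass (adjusted over the list alone, 3 higher and 2 lower). The receptor gene Cd22 fell by 0.51 ± 0.058 (SE), the phosphatase gene Ptpn6, which encodes SHP1, fell by 0.22 ± 0.048, and Cd5 rose by 0.22 ± 0.045. The camera adjusted p was 0.767, with a median log2 fold change of 0.0025 and a downward test direction, so median and test differed in sign. Inppl1, which encodes the related phosphatase SHIP2, had a log2 fold change of -0.036 (adjusted p = 0.648), turning to 0.0038 after quantile normalization. Of 19 genes of B cell maturation and antigen presentation, 2 were higher, 2 lower and 15 did not pass (adjusted over the list alone, 5 higher and 3 lower). Dntt, which encodes terminal transferase, and the invariant chain gene Cd74 rose by 0.33 and 0.28, while the recombinase gene Rag2 and the chemokine receptor gene Cxcr5 had log2 fold changes of -0.50 and -0.29. The camera adjusted p was 0.738. Cd22 passed with each array left out, and the other genes called here lost their calls with at least 3 of the 6 arrays left out.

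For the ERK-induced, FOXO-activated, p53 target, cell death, unfolded protein and antioxidant lists, single genes passed while camera called no list; fry called the p53 target (adjusted p = 0.0244), unfolded protein and ATF4 response (0.0375) and antioxidant and NRF2 target lists (0.0111). Of 24 ERK-induced immediate early and feedback genes, 2 were higher, 3 lower and 19 did not pass (adjusted over the list alone, 4 higher and 6 lower; camera adjusted p = 0.738, with a median log2 fold change of 0.030 and a mean of -0.013). The cyclin D1 gene Ccnd1 fell by 0.85 ± 0.044 (SE) on the log2 scale and the feedback inhibitor gene Spred1 by 0.19 ± 0.043, while the immediate early genes Fosb and Egr1 rose by 0.66 and 0.38. Ccnd2, which encodes cyclin D2, had a log2 fold change of 0.084 (adjusted p = 0.207), negative after centring. Of 23 FOXO-activated genes, 3 were lower, 0 higher and 20 did not pass (adjusted over the list alone, 1 higher and 3 lower; camera adjusted p = 0.746): Rag2 (-0.50), the coactivator gene Cited2 (-0.41) and the cyclin G2 gene Ccng2 (-0.33). For this list the median was 0.035 and the test direction upward, while the mean was -0.0028. Of 24 p53 target genes, 3 were higher, 0 lower and 21 did not pass (adjusted over the list alone, 6 higher and 0 lower): Sesn2 (0.30), Btg2 (0.25) and Trp53inp1 (0.20). The p53 list did not pass by camera (adjusted p = 0.0615), but did after quantile normalization (0.00314), after loess (0.00265), with the stricter filter on dim genes (0.00611), and without ERT2 control array 1 (0.0499), ERT2 control array 2 (0.0440) or the array labelled Cre-ERT2 2 (0.0241). Cdkn2a, which encodes p16 and p19Arf, had a log2 fold change of -0.11 (adjusted p = 0.161). Ccnd1, Fosb and Egr1 passed with each array left out in turn, and Rag2, Cited2, Ccng2, Sesn2, Btg2, Trp53inp1 and Spred1 in at most 4 of 6 such fits.

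Of 22 BCL2 family and cell death genes, 2 were higher, 0 lower and 20 did not pass (adjusted over the list alone, 3 higher and 0 lower; camera adjusted p = 0.511), namely the BH3-only genes Bmf (0.33) and Hrk (0.28). Of 26 unfolded protein and ATF4 response genes, 1 was higher, 4 lower and 21 did not pass (adjusted over the list alone, 3 higher and 7 lower; camera adjusted p = 0.150). Chac1, which encodes a glutathione-degrading enzyme, had a log2 fold change of -0.56, the asparagine synthetase gene Asns -0.42 and the serine pathway gene Shmt2 -0.20. The list passed by camera without the filter on dim genes (adjusted p = 0.0422). Of 21 antioxidant and NRF2 target genes, 2 were higher, 1 lower and 18 did not pass (adjusted over the list alone, 3 higher and 2 lower; camera adjusted p = 0.251): Hmox1, which encodes heme oxygenase 1 (0.27), Txnrd1, which encodes a thioredoxin reductase (0.26), and the glutathione transferase gene Gstm1 (-0.30). With the stricter filter on dim genes this list passed by camera (0.0336). With single arrays left out, Chac1 and Asns passed each time, and Bmf, Hrk, Shmt2, Hmox1, Txnrd1 and Gstm1 in at most 2 of 6 fits.

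Marker genes of other cell types were measured alongside, and several were higher in the arrays labelled Cre-ERT2, as were 1 or more members of the interferon, STAT5 and NF-kB lists. Several of these markers were dim, with control means of 8.03 for Fn1, 8.08 for Cebpa and 7.98 for Zap70. Lyz2 (9.24) and Cd2 (11.01) were brighter. Random lists matched on expression had median mean log2 fold changes of 0.071, 0.072 and 0.088 for the myeloid, stromal and T and NK lists. The means of these lists were 0.15, 0.17 and 0.091. Of 30, 21 and 23 markers written, those not tested had no usable probe set or were too dim. Of 16 myeloid marker genes tested, 4 were higher, 0 lower and 12 did not pass (adjusted over the list alone, 5 higher and 0 lower): the lysozyme genes Lyz2 (0.79 ± 0.099, SE) and Lyz1 (0.36) and the transcription factor genes Cebpa (0.27) and Cebpe (0.21). For the myeloid list the camera adjusted p was 0.0224, and adjusted p = 0.233 with an estimated correlation. Of 13 stromal and fibroblast marker genes, 2 were higher, 0 lower and 11 did not pass (adjusted over the list alone, also 2 higher and 0 lower), the matrix genes Fn1 (0.40 ± 0.049) and Sparc (0.24). For the stromal list it was 9.72e-04, and adjusted p = 0.348 with an estimated correlation. Of 13 T and NK cell marker genes, 2 were higher, 1 lower and 10 did not pass (adjusted over the list alone, 7 higher and 1 lower), with Zap70 (0.23) and Cd5 (0.22) higher and the adhesion gene Cd2 (-0.64 ± 0.053) lower. Its camera adjusted p was 0.0304, and adjusted p = 0.233 with an estimated correlation. Of 8 erythroid and megakaryocyte marker genes, 0 were higher and 0 lower by limma's test and 1 had an unadjusted p under 0.05 (adjusted over the list alone, also 0 and 0; camera adjusted p = 0.358). The myeloid call ended after quantile normalization (0.116), after loess (0.128), with array weights (0.0801), with the stricter filter on dim genes (0.0597) and without ERT2 control array 3 (0.0510), and the T and NK call after quantile normalization (0.315), after loess (0.351), with array weights (0.0508), with the stricter filter on dim genes (0.848, with its mean shift turned to -0.18) and without the array labelled Cre-ERT2 2 (0.0810). Lyz2, Fn1 and Cd2 passed with each array left out, Zap70 in 0 of 6 such fits, and Lyz1, Cebpa, Cebpe, Sparc and Cd5 in at most 4.

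**Figure D2:**
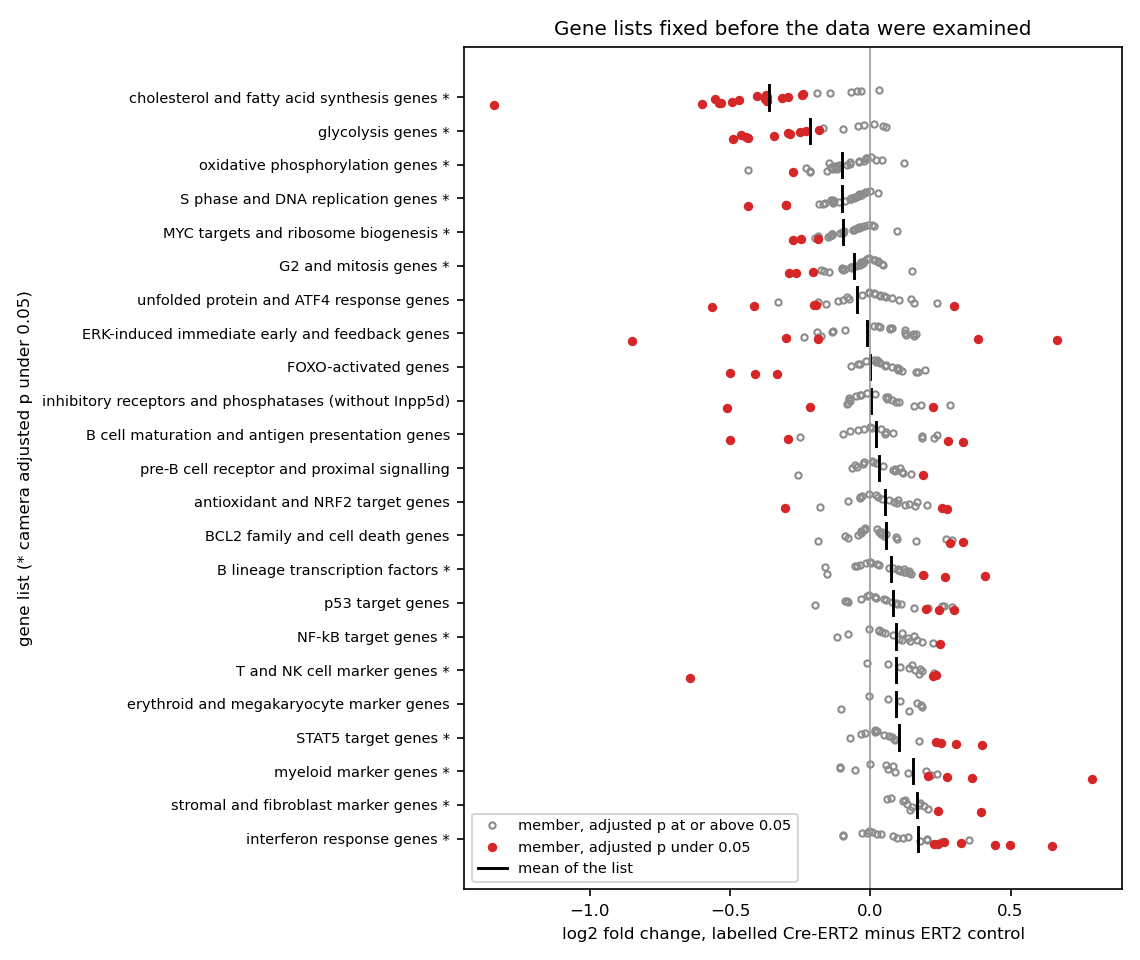
Log2 fold change (horizontal axis, arrays labelled Cre-ERT2 minus ERT2 control arrays, 3 of each) of every tested member of the 23 gene lists (vertical axis); red circles are members with an adjusted p under 0.05, open circles other members and black bars the list mean, and a star marks lists with a camera adjusted p under 0.05. Cholesterol and fatty acid synthesis genes have the lowest mean, -0.36, and interferon response genes the highest, 0.17, and neither list changed direction under another scaling of the arrays.

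The difference between the groups varied with brightness. With all named genes put in 10 equal bins by mean log2 value, the median log2 fold change was between 0.045 and 0.12 in the 6 dimmest bins and between -0.057 and -0.013 in the 4 brightest. The arrays labelled Cre-ERT2 did not share this pattern alike. In bins 2 to 5, the median deviation of genes from their mean over all 6 arrays was 0.063 to 0.065 in array 1 and 0.098 to 0.12 in array 2, but -0.019 to -0.0060 in array 3. In bins 7 to 9 it was -0.088 to -0.051 in array 2, -0.0082 to -0.0043 in array 1 and 0.0044 to 0.015 in array 3. After loess between arrays, a setting chosen after seeing the data, these medians lay between -0.039 and 0.029. Of the 13 lists called, 7 passed in each setting run with the preset correlation: cholesterol and fatty acid synthesis, glycolysis, MYC targets and ribosome biogenesis, S phase, oxidative phosphorylation, interferon response and stromal markers. With the correlation estimated for each list, 0 of 23 lists passed by camera, and 3 had an unadjusted p under 0.05. Calls were also lost where the estimate was near or below the preset of 0.01. The estimate was -0.0072 for B lineage transcription factors, with an unadjusted camera p of 0.020 preset and 0.060 estimated. For NF-kB targets it was 0.011 (0.022 preset and 0.085 estimated). A lost call in this setting therefore does not by itself show that the genes of a list are correlated. The fry test, which asks whether the genes of a list move in a common direction without comparing them with other genes, called 15 lists.

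**Figure D3:**
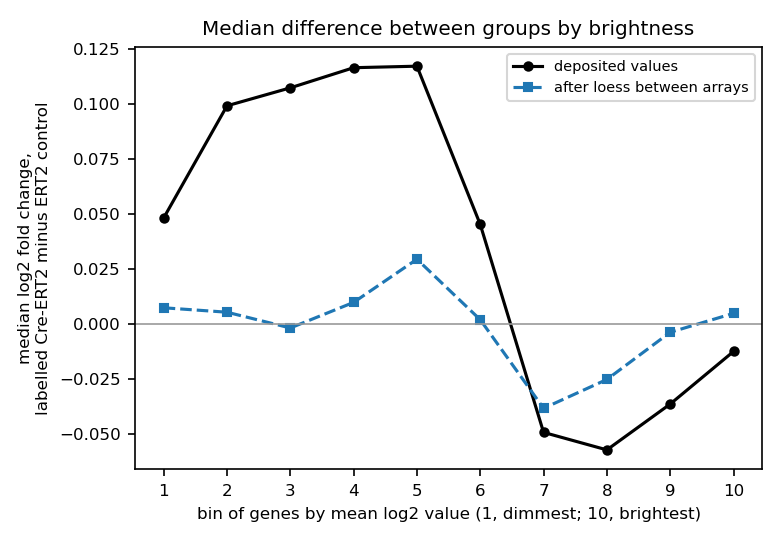
Median log2 fold change (vertical axis, arrays labelled Cre-ERT2 minus ERT2 control arrays) in 10 equal bins of genes ordered by mean log2 value (horizontal axis, dimmest at 1), for the deposited values (black circles) and after loess between arrays (blue squares). The medians of the deposited values span -0.057 to 0.12, and those after loess -0.039 to 0.029.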

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

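The tests of probe sets with no gene name, of the Inpp5d interval and of a ceiling, of Xist after loess, of the Y-linked and nuclear-retained RNAs, of the lists against brightness and of other splits of the arrays were chosen only after the result they bear on had been seen. Outside the genes compared, 7961 probe sets with no gene name here were tested with limma, and 11 of them were higher and 12 lower in the arrays labelled Cre-ERT2 at an adjusted p under 0.05. This is a smaller share than the 7.62% of named genes tested. The median log2 fold change of the unnamed probe sets was 0.079, against 0.026 for the named genes. What they measure is not known here, and none was followed up.

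The target of the deletion, Inpp5d, was not lower in the arrays labelled Cre-ERT2. The tables argue against loss of the whole transcript from most cells, since the lower end of the 95% interval of its log2 fold change was 0.064. They also argue against a ceiling of the whole array at this brightness, since 1 gene as bright in the controls, Scd2 (13.70), fell by 0.60. Where the Inpp5d probes themselves saturate was not tested. A transcript that lost its deleted exons but kept the probed part, incomplete recombination and exchanged group labels may each remain open and were not tested.

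Xist was 1.62-fold higher in the arrays labelled Cre-ERT2 (log2 values of 12.76, 12.63 and 12.48 against 11.92, 11.85 and 12.02), and of 3 Y-linked genes tested Eif2s3y (-0.30, adjusted p = 0.0309) and Uty (-0.26, adjusted p = 0.0463) were lower and Kdm5d (-0.11, adjusted p = 0.269) did not pass. The intensity-dependent difference between arrays is argued against as the whole cause, since the Xist difference was 0.72 after loess. A larger share of female cells may contribute, since the mean of the Y-linked genes lay at percentile 2.77 of random lists matched on expression, but the 5 escape genes lay at percentile 59.0, which decides nothing. A larger share of nuclear-retained RNA may contribute too, since Airn (0.25, adjusted p = 0.212) and Meg3 (0.23, adjusted p = 0.159), neither of which passed, had a mean at percentile 98.15. Malat1 had risen as well, but its rise was seen first. After loess neither Airn (0.24, adjusted p = 0.249) nor Meg3 (0.12, adjusted p = 0.438) passed. Of other nuclear RNAs, Scarna13 rose (0.67) while the small nucleolar RNA Snord118 fell (-1.01). Xist passed with each array left out, Malat1 in 1 of 6 such fits, and both explanations stay open.

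The 13 lists called were set against the dependence of the group difference on brightness. It is argued against as the whole cause for 10 of these lists, since all 10 were called in the same direction after loess and had means outside the central 95% of random lists matched on expression. Matched lists treat genes as independent, and 0 of 23 lists passed with an estimated correlation. After loess the mean shift shrank from -0.12 to -0.065 for S phase, -0.066 for MYC targets and -0.075 for oxidative phosphorylation genes. It shrank from 0.15 to 0.098 for stromal markers, and also for the cholesterol, glycolysis and NF-kB lists. It grew for the STAT5, interferon and B lineage lists. For T and NK cell marker genes the dependence on brightness may be the whole cause, since the list mean lay at percentile 53.19, and the mean shift against all genes went from 0.074 (SD of members 0.23) to 0.015 after loess, which ended the call. Myeloid marker genes (percentile 99.56, mean shift 0.14 before and 0.088 after loess, SD of members 0.22) and G2 and mitosis genes (percentile 2.43, mean shift -0.076 before and -0.028 after, SD of members 0.093) cannot be told apart from it, because their calls ended as the shift shrank, although their means were extreme for their brightness. The biological difference that the design names, Cre activity on floxed Inpp5d, was not tested apart from these.

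The number of genes called was 1140 in the real grouping and 0 in each of the other 9 of the 10 ways to split the 6 arrays into 3 and 3, so that 1 split, the real one, gave as many; with 10 splits no share under 0.05 can be reached. Each other split mixes both labels within a group, so any difference between the labels adds to the spread within groups. The 0 calls in those splits therefore do not decide the question.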

How the results depend on the processing

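Loess between arrays was the only alternative chosen after seeing the data. Counts of genes called (higher, lower) were 437 (187, 250) with no filter on dim genes, 3020 (223, 2797) with arrays centred on their medians, 2147 (849, 1298) with trend and robust estimation, 3993 (2273, 1720) with array weights, 9 (1, 8) at 2-fold or more, 143 (52, 91) at adjusted p under 0.01 and 146 (54, 92) over all 26667 probe sets. They were 1563 (552, 1011) with the 50th percentile filter, 994 (365, 629) with quantile normalization, 1171 (470, 701) with loess and 1147 (520, 627) with the mean of probe sets, against 1140 (523, 617) as reported. Of the 1140 genes, 413 were shared with no filter, 798 centred, 1092 with trend and robust estimation, 1140 with array weights, 890 with the 50th percentile filter, 820 with quantile and 901 with loess. Leaving out each array gave 116 (without ERT2 control 1) to 3042 (without Cre-ERT2 3) genes, 40 to 1696 higher and 76 to 1346 lower; of 84 named genes called, 34 kept their call in all 6 such fits. With the replicate number as a block the counts were 147 (47, 100), 145 of them shared, and the list of B lineage transcription factors lost its call (adjusted p = 0.0698), the other 12 lists keeping theirs. Deviations of same-numbered arrays correlated at 0.069, -0.17 and -0.40 across genes, and 1 of 6 arrays matched its own number best. No sign of pairing by number was seen. A shared effect could still be hidden by array differences that vary with brightness, and the labels do not state a pairing. Inpp5d passed at 0.16 with the 50th percentile filter (0.0283), quantile normalization (0.16, 0.0485), trend and robust estimation (0.16, 0.00364), array weights (0.16, 0.0199) and loess (0.17, 0.0367), within adjusted p from 0.00364 to 0.595 over all settings. With an estimated correlation 0 lists were called. Camera's direction turned, with no call in that setting, for inhibitory receptors (mean shift 0.020 at the 50th percentile, 0.0074 with quantile, 0.010 with loess), B cell maturation (-0.018 with no filter; -0.016 to 0.031 with an array left out) and T and NK (-0.18 at the 50th percentile), where the mean shift changed sign too. It also turned for FOXO (-0.035 with no filter, -0.020 centred, -0.037 to -0.0027 with an array left out), ERK (-0.052 to -0.0092 with an array left out) and erythroid (0.0055 at the 50th percentile), where the mean shift kept its sign. The FOXO mean shift, -0.020 in the reported setting, became 0.014 at the 50th percentile, 0.0049 with quantile and 0.0082 with loess, and that of pre-B cell receptor genes -0.0031 with no filter, without a turn of camera's direction. Genes that turned, none called, were Inppl1 (0.0038, quantile), Syk (-0.058, centred), Blnk (-0.013, centred), Btk (-0.084, centred; -0.014 to 0.060 with an array left out), Bcl6 (-0.0072, quantile; -0.0023, centred), Pax5 (0.0072, quantile; 0.020, weights; 0.011, loess; -0.028 to 0.023 with an array left out) and Ccnd2 (-0.018, centred). The cause of these changes, the stronger Inpp5d call at the 50th percentile among them, was not tested. Over the 15 settings of filter, scaling, model or arrays, the stricter thresholds and the test of all probe sets left out, from 35 to 84 of the named genes called kept their calls, 0 of them with the sign turned, and from 9 to 14 lists were called with the preset correlation. Signal over background could not be assessed from summarized values.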

Other observations

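The groups of genes in this part were written after the data had been seen, and of its tests only that of the hypoxia-induced genes was set down before its result was seen. Probe sets of the locus of miR-17-92, an oncogenic microRNA cluster under the control of MYC, were lower in the arrays labelled Cre-ERT2. All 6 tested probe sets of the locus passed limma's test: the host transcript Mir17hg had a log2 fold change of -0.30 ± 0.049 (SE, adjusted p = 0.0170), Mir18 -0.78 ± 0.13 (adjusted p = 0.0170), Mir19b-1 -0.51 ± 0.12 (adjusted p = 0.0412), Mir20a -0.36 ± 0.090 (adjusted p = 0.0491) and Mir17 -0.35 ± 0.064 (adjusted p = 0.0237), besides Mir19a at -1.10. The 6 kept their direction and call after loess, at adjusted p from 0.00340 for Mir17hg to 0.0329 for Mir20a. They lie in 1 primary transcript and are not independent.

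Of 13 tested lipid genes outside the synthesis list, 8 were lower, 0 higher and 5 did not pass in the arrays labelled Cre-ERT2. The desaturase gene Fads2 had a log2 fold change of -0.77 ± 0.043 (SE, adjusted p = 1.56e-04), the phospholipid transfer gene Pltp -0.73 ± 0.055 (7.64e-04), the lipid transporter gene Mfsd2a -0.59 ± 0.068 (0.00456) and the sterol exporter gene Abcg1 -0.56 ± 0.052 (0.00206). Fads3 (-0.38), Hsd17b7 (-0.27), Aacs (-0.25) and Fads1 (-0.20) also fell. Since Abcg1 exports sterols whereas the synthesis genes make them, the genes that fell were not limited to synthesis. The list was picked with knowledge of the data and is no independent evidence.

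A hypothesis for the fall of the glycolysis genes is a lower response to hypoxia through HIF, which induces many of them. Of 19 tested hypoxia-induced genes outside the glycolysis list, 5 were lower, 0 higher and the others did not pass. The 5 lower genes were Gbe1 (-0.39, adjusted p = 0.0172), Bnip3 (-0.32, adjusted p = 0.0237), Ankrd37 (-0.27, adjusted p = 0.0361), Mif (-0.20, adjusted p = 0.0396) and Egln1 (-0.20, adjusted p = 0.0388). After loess 4 of the 5 kept their calls, and Egln1 did not pass (-0.17, adjusted p = 0.0559). The mean log2 fold change of the 19 genes was -0.11 and lay at percentile 0.33 of random lists matched on expression, which may point that way. Vegfa (-0.034, adjusted p = 0.594) and Egln3 (0.10, adjusted p = 0.242), both induced by HIF, did not pass. Like Egln3, Adm (0.19, limma adjusted p = 0.126), P4ha2 (0.062, 0.648) and Ndrg1 (0.026, 0.670) had positive log2 fold changes without passing. The remaining genes that did not pass, Vegfa among them, had negative ones. MYC, which also induces glycolysis genes and fell here, remains an untested alternative.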
